A study of Homo sapiens with 8 samples.

How the data were processed

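Gene expression was measured on 8 one-colour Affymetrix arrays, 1 per RNA sample, in human embryonic stem cells. Per the labels, a clonal line over-expressing SOX7 was derived from the line CA1 and a clonal line over-expressing SOX17 from the line CA2, with 2 clones each, and each over-expressing culture is set beside the parental control culture of the same clone. This gives 4 groups of 2 arrays: SOX7 over-expressing, SOX7 control, SOX17 over-expressing and SOX17 control. By their titles, all over-expressing arrays are marked Cre and all control arrays NoCre. Per the labels' protocols, the cells were kept on mouse feeder fibroblasts in medium with serum replacement and FGF2, at passages 2 to 4 and 80% confluence, under puromycin or G418. The labels do not say which arrays had which drug. They give 8 µg of total RNA per sample. The transgene and the parent line go together in this design, so that a difference between the SOX7 and SOX17 responses belongs to either.

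The deposited values are intensities on a linear scale, 1 value for each of 54675 probe sets and each array, with no value missing. The authors made them with MAS5, per the submitters' processing notes. The version and the scaling target are not given in the sources used here. The mean of the probe sets without the highest and lowest 2% was 500.1 on every array, so that each array had been scaled to a common level. Detection calls were not used here. Probe sets were named through the platform's annotation of 2016. The annotation gave 1 gene symbol for 41097 probe sets and several for 1801, while 11777 had none here. The 62 control probe sets were left out of all tests. No symbol changed when updated through its gene identifier, and 54 single symbols without a match were kept as annotated. The named probe sets covered 19775 symbols. No gene is named from a probe set with several symbols, which leaves out POU5F1. No genome build was used, so that no coordinates are given.

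Values were taken as log2(intensity + 16) with no further scaling. Probe sets at or above the median of their array on at least 2 of the 8 arrays were kept, which left 31744, of which 26050 carried 1 symbol. The probe set with the highest mean stood for each gene, and 14036 genes were tested. A fold change on this scale understates the change of genes with low intensity. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit with 4 group means, then eBayes with a trend of the variance on the mean level). The fit had 4 residual degrees of freedom and 8.4 from the prior. Benjamini-Hochberg adjusted p-values under 0.05 over all genes tested were taken as calls, and errors of log2 changes are limma's moderated standard errors (SE). Contrasts were the SOX7 response (over-expressing minus control), the SOX17 response, the difference between them (SOX17 minus SOX7) and the difference between the 2 controls (CA2 minus CA1). Means of intensities are given with the standard deviation (SD) of 2 clones. Clones served as replicates. The p-values measure the spread between the clones within a group, pooled over the 4 groups of both lines.

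The 20 gene lists, holding 393 entries of which 349 are distinct, were written from textbook knowledge, and 303 entries (267 distinct genes) were measured. The lists covered pluripotency, definitive endoderm, extraembryonic endoderm, primitive streak, mesoderm, ectoderm, trophoblast, endothelium, primordial germ cells, liver and gut, basement membrane, fibroblasts, epithelial adhesion, mesenchymal transition, the Nodal, Wnt and BMP pathways, cell cycle, p53 targets and stress, and housekeeping genes. They were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry, each adjusted over the 20 lists within a contrast. Camera compares a list with the other genes. The fry p-values test whether the genes of a list move, on balance, in one direction, and do not compare the list with other genes. Counts within a list are given over all genes and also adjusted over the list alone.

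The genes named are, for each response, the 12 largest called rises and the 12 largest called falls with the same sign in both clones, or all where fewer passed. For the difference between the responses and the difference between controls they are the 8 largest called in each direction. Up to 4 members of each list with the smallest p-values per contrast and a fixed set of lineage markers were added. The sample groups, this rule, the lists, the fits and most of the alternatives were fixed before the data were examined. Genes named outside the rule are marked as chosen after their values were seen. Genes whose level could give the sex of a line are left out.

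The pairing of arrays comes from the labels, which tie an over-expressing culture and its control to the same clone. Deviations from the group means of arrays with the same clone number correlated across genes at r = 0.30 for SOX7 and r = 0.307 for SOX17. Between the lines, arrays with the same number correlated at 0.219 (controls) and 0.12 (over-expressing). Part of the correlation is therefore not particular to the clone pair. The poly-A spike-in controls also split the arrays into clone 1 of both lines, SOX7 clone 2 and SOX17 clone 2. A block for the clone and a block for these preparation batches gave identical fits of both responses and of their difference, and the blocked counts are given beside the main ones. The fit without the block was the main one. Blocked fits leave fewer residual degrees of freedom than the main fit. Their p-values measure how far the responses of the 2 clones of a line differ, pooled over both lines.

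The procedure was tested on simulated data, with 200 genes changed in each of 5 draws. Each probe set was drawn around its mean over all 8 arrays with its moderated spread, independently of the others. Effects of clone and batch and correlation between genes were thus absent, so that these error rates, for genes and lists, need not hold for the real arrays. For the SOX7 contrast, with a median of 14104 genes tested, 41.6% of genes changed 2-fold and 83.5% of genes changed 4-fold were recovered, and 7% of calls were false. For the SOX17 contrast, with 14107 genes tested, these values were 42.8%, 80.4% and 8.5%. A shifted gene list was found in 5 of 5 draws for either contrast, with 2 and 5 other lists called in all draws together. The number of arrays limits the precision of every comparison.

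Alternatives were pseudocounts of 1 and 64, no filter or a filter at the 75th percentile, quantile normalization, median centring, the mean of all probe sets per gene, every probe set tested, no variance trend, only the arrays of a contrast, the clone as a block, other thresholds, and each array left out in turn. Leaving out each clone pair and a batch block for the controls were added after seeing the data. Kept probe sets without a single symbol, 5694 in all, were tested only in that setting. Tables were handled with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.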

Results

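Transcript levels were compared in human embryonic stem cells labelled as over-expressing SOX7 or SOX17, transcription factors of the SOXF family with roles in endoderm and blood vessels, and in their parental controls. There were 2 clones per arm. The SOX7 clones came from the embryonic stem cell line CA1 and the SOX17 clones from the line CA2. Median intensities of the 8 arrays lay between 84.3 and 137, at a common trimmed mean. The 3'/5' ratios of the ACTB control probe sets, a sign of RNA integrity, were 1.23 to 1.43, and those of GAPDH 0.930 to 1.27. The poly-A spike-in dap, added during RNA labelling, read 1057 to 1739 on the clone 1 arrays of both lines, 4642 and 5357 on the SOX7 clone 2 arrays and 114 and 123 on the SOX17 clone 2 arrays. The p-values rest on clones as replicates and measure the spread between them. By the spike-in, the 2 clones of each group were also prepared apart, so that this spread includes that between preparations.

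SOX17 transcript was higher in the SOX17 over-expressing clones than in their controls, and SOX7 transcript was not detectably higher in the SOX7 over-expressing clones. The SOX17 probe set tested had an intensity of 2335 ± 299.8 (SD, n = 2) against 802 ± 208 (SD, n = 2) in the controls, a log2 change of 1.54 with a 95% interval from 0.81 to 2.27 (limma adjusted p = 0.0185). A further SOX17 probe set went from 479.6 to 1309, with an adjusted p of 0.0728 among all probe sets. The SOX7 probe set tested had an intensity of 78.5 ± 12.8 (SD, n = 2) on the arrays labelled SOX7 over-expressing and 93.0 ± 30.04 (SD, n = 2) on their controls (log2 change −0.18, adjusted p = 0.958). The other SOX7 probe set lay below the filter, at 41.3 and 35.7. The position of the SOX7 and SOX17 probe sets relative to the transgenes is not given in the sources used here. The SOX7 probe sets therefore do not check the label. How much of the SOX17 rise comes from the transgene is not known either. In the SOX7 arm, SOX17 was at 929.9 against 509.7 in clone 1 and at 391.9 against 551.7 in clone 2. SOX18, the remaining SOXF gene, lay below the filter and was not tested, with 80.5 ± 30.7 against 28.5 ± 8.02 in the SOX7 arm and 85.2 ± 30.9 against 36.9 ± 9.88 in the SOX17 arm (SD, n = 2).

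The first question was which genes change when SOX7 is over-expressed. APOA2, a lipoprotein component made by visceral endoderm and liver, rose from 602.5 ± 51.0 to 6015 ± 619 (SD, n = 2; log2 change 3.28, SE 0.41, adjusted p = 0.00293). HHEX, a homeobox factor of anterior endoderm, rose from 180.8 ± 7.15 to 1085 ± 427 (SD, n = 2; log2 change 2.43, SE 0.30, adjusted p = 0.00293). ACSL1, which activates long-chain fatty acids, rose by a log2 value of 2.89 (adjusted p = 0.00015), and DLK1, an imprinted Notch-like ligand, by 2.70 (adjusted p = 0.000152). NTS, the neurotensin precursor, fell from 15236 ± 543 to 1332 ± 126 (SD, n = 2; log2 change −3.50, adjusted p = 1.54e-05), and ANXA1, a phospholipid-binding annexin, by a log2 value of −3.72 (adjusted p = 0.000819).

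In all, 83 genes rose and 26 fell with SOX7, 109 of 14036. Unadjusted p-values under 0.05 were found for 1306 genes, where chance gives 701.8. At least a 2-fold change was seen in 108 of the 109. With the clone as a block, 441 genes passed (281 higher, 160 lower), among them all 109. Without the variance trend 8 passed, and 33, 22 and 19 passed without the clone 1 over-expressing array, the clone 1 control or the clone 2 control. Centring each array on its median gave 64 rises and 34 falls.

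Among the other large rises with SOX7 were NOS2, the inducible nitric oxide synthase (log2 change 4.31, SE 0.67, adjusted p = 0.0105), the proteoglycan gene SPOCK3 (4.15), the long noncoding RNA LINC00261, a neighbour of FOXA2 (4.14), the hedgehog ligand IHH (3.72), IGFBP5, which binds insulin-like growth factors (3.48), APOA1, the main protein of high-density lipoprotein (3.29), PLSCR2 (3.28), LGI2 (2.98), the semaphorin SEMA6D (2.86) and SHISA2 (2.50). The caveolar coat genes CAV1 (−1.89) and CAV2 (−2.05) fell together with the antiviral gene TRIM22 (−2.30), LY6K (−2.93), the mitochondrial thioredoxin reductase TXNRD2 (−2.05), the secreted phosphoprotein SPP1 (−1.81) and the formin DIAPH2 (−1.73).

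Of 22 definitive endoderm genes measured, 3 rose with SOX7 (HHEX, SHISA2 and the receptor KIT, log2 change 1.88), none fell and 19 did not pass, and 14 were higher when adjusted over the list alone. The mean log2 change was 1.16 and 21 members were positive (camera adjusted p = 6.1e-14, and adjusted p = 0.28 with an estimated correlation; fry adjusted p = 0.159). A block for the clone gave 9 rises among them. FOXA2, a pioneer factor of endoderm, had a log2 change of 1.79 (adjusted p = 0.0719, and 0.00896 with the clone as a block). The changes of CXCR4 (1.58, adjusted p = 0.145), CER1 (1.36, 0.0689) and GATA4 (1.27, 0.0542) did not pass either, and those with the block did, at 0.00803, 0.00581 and 0.0128. GATA6 had a log2 change of 0.90 (adjusted p = 0.363).

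Of 23 extraembryonic endoderm genes, 3 rose with SOX7 (APOA1, APOA2 and the laminin chain LAMB1, log2 change 1.07) and none fell, with 13 higher and 3 lower adjusted over the list alone and 7 higher and 2 lower over all genes with the clone as a block (camera adjusted p = 1.39e-06, and adjusted p = 0.28 with an estimated correlation). Of 21 basement membrane genes, LAMB1 and the perlecan gene HSPG2 (1.59) rose, 6 were higher over the list alone and 5 with the block (camera adjusted p = 0.000153, and adjusted p = 0.534 with an estimated correlation). None of 13 mesenchymal transition genes passed over all genes without the block, and 2 were higher over the list alone and with the block (limma; camera adjusted p = 0.00582, mean 0.47, and adjusted p = 0.534 with an estimated correlation).

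Few pluripotency genes passed the test with SOX7. Of 23 measured, the neuropeptide gene GAL was lower (log2 change −1.52, with its other probe set of opposite sign) and 22 did not pass, where the block gave 3 falls. The list's mean was −0.21 (camera adjusted p = 0.00945, and adjusted p = 0.28 with an estimated correlation). SOX2 had a log2 change of −0.12 (adjusted p = 0.917) and NANOG of −0.20 (adjusted p = 0.844). Of 16 p53 targets and stress genes, ASNS, the asparagine synthetase, fell (−1.09), and 3 were lower over the list alone and with the block (camera adjusted p = 3.78e-05, mean −0.43, and adjusted p = 0.28 with an estimated correlation). None of 15 BMP pathway genes passed over all genes without the block, and 3 were lower over the list alone and with the block (limma; mean −0.28, camera adjusted p = 0.0438, 0.0826 with the clone as a block, and adjusted p = 0.534 with an estimated correlation). The 20 cell cycle genes, none of which passed in limma, had a camera adjusted p of 0.0545, of 0.0264 with the clone as a block, and an adjusted p = 0.7 with an estimated correlation.

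The remaining lists were not called with SOX7. Single members passed in several of them: PAX6 in the ectoderm list (log2 change 2.01, list camera adjusted p = 0.97), VIL1 of intestinal microvilli in the liver and gut list (2.47, 0.393), DKK1 (1.70) and FZD5 (1.61) in the Wnt list (0.186), the activin antagonist FST in the Nodal list (1.22, 0.75), KRT19 in the epithelial list (1.11, 0.339) and KIT in the primordial germ cell list (0.198). The angiopoietin receptor TEK was lower in the endothelium list (−1.31, 0.569), and the collagen COL3A1 was higher in the fibroblast list (1.37, 0.75). No member of the streak list (0.426), the mesoderm list (0.612), the trophoblast list (0.426) or the housekeeping list (0.579) passed in limma over all genes, where 1 trophoblast gene was higher over the list alone. Adjusted over the list alone, 3 Wnt genes were higher and 2 lower, 3 Nodal genes higher and 2 lower, 3 epithelial and 2 fibroblast genes higher, and 1 liver and gut gene higher and 1 lower. The block gave 2 Wnt genes higher and 2 lower over all genes, 3 Nodal genes higher and 2 lower, 3 epithelial genes higher, 2 fibroblast genes higher and 1 lower, 1 trophoblast gene higher, and 1 higher and 1 lower in each of the ectoderm and the liver and gut lists. The mean of the fibroblast list, written for the feeder cell type, was 9.79 and 9.20 (log2) on the SOX7 arrays and 9.47 and 9.25 on their controls.

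The second question was which genes change when SOX17 is over-expressed. APOA1 rose from 140.6 ± 108 to 14085 ± 9135 (SD, n = 2; log2 change 6.52, SE 0.51, 91.7-fold, adjusted p = 5.41e-05). FOXA2 rose from 206.5 ± 154 to 2464 ± 36.1 (SD, n = 2; log2 change 3.68, SE 0.41, adjusted p = 0.000281), and GATA4 from 209.7 ± 29.8 to 1919 ± 355 (SD, n = 2; log2 change 3.09, SE 0.27, adjusted p = 8.47e-05). SOX2, a core pluripotency factor, fell from 14875 ± 3139 to 7628 ± 1193 (SD, n = 2; log2 change −0.95, adjusted p = 0.0173), and FGF2, a growth factor that sustains human embryonic stem cells, by a log2 value of −1.51 (adjusted p = 0.00225).

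With SOX17, 495 genes rose and 174 fell, 669 of 14036. The falls depended on the variance trend more than the rises, with 172 rises and 20 falls left without it. Unadjusted p-values under 0.05 were found for 2578 genes, and 552 of the calls changed at least 2-fold. With the clone as a block 1971 genes passed (1098 higher, 873 lower), among them all 669. Without the variance trend 192 passed, and without the clone 1 control 360.

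**Figure D1:**
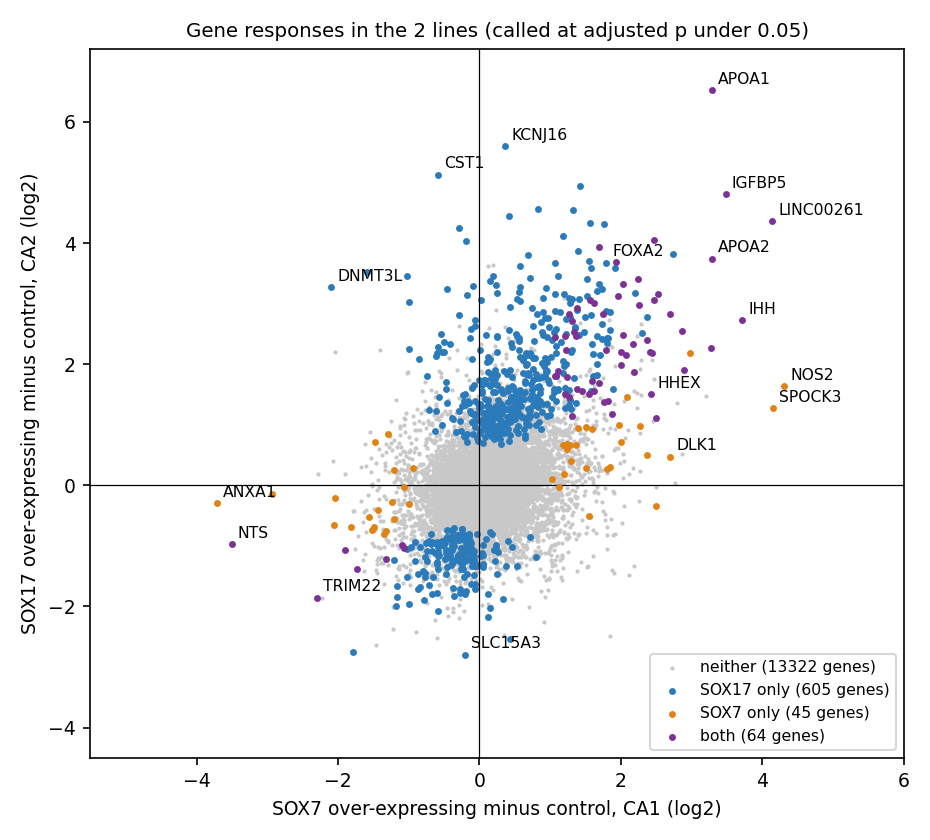
Log2 change with SOX7 (horizontal) against log2 change with SOX17 (vertical) for the 14036 genes tested, each point a gene and each colour showing in which response it was called. The 64 genes called in both lie in the upper right, 57 of them, or in the lower left, 7 of them.

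The largest rises with SOX17 after APOA1 included the potassium channel gene KCNJ16 (log2 change 5.6, from a control level of 17.6), the salivary cystatins CST1 (5.13) and CST4 (4.26), GASK1B (4.95), IGFBP5 (4.81), the atrial myosin light chain MYL7 (4.55), the Wnt agonist RSPO3 (4.55), TNNC1, the troponin C of cardiac and slow muscle (4.45), LINC00261 (4.36), FOXQ1 (4.33) and the Wnt antagonist FRZB (4.31). The largest falls were SLC15A3 (−2.80), the galectin gene CLC (−2.75), the class II antigen gene HLA-DRA (−2.55), the lysine-degrading AASS (−2.18), GALNT3 (−2.08), the pigment cell genes GPR143 (−2.03) and PMEL (−1.88), PTPRZ1 (−2.0), CNRIP1 (−1.96), CALCB (−1.90), TRIM22 (−1.85) and the tryptophan-degrading enzyme IDO1 (−1.85). On the SOX17 over-expressing arrays SLC15A3, CLC and HLA-DRA were at 15.5, 37.9 and 14.5, so that the sizes and ranks of their falls depend on the constant added.

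Of the 22 definitive endoderm genes, 14 rose with SOX17, none fell and 8 did not pass, with 18 higher and 1 lower adjusted over the list alone and 17 higher over all genes with the clone as a block. Besides FOXA2 and GATA4, the risers included the chemokine receptor CXCR4 (log2 change 3.59), the Nodal and Wnt antagonist CER1 (2.60), EOMES (1.90), KIT (1.18) and GATA6 (2.48, with another probe set of opposite sign). SOX17 itself is 1 of the 14. The mean change was 1.86 (camera adjusted p = 1.91e-18, and adjusted p = 0.124 with an estimated correlation; fry adjusted p = 0.017).

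Of 23 extraembryonic endoderm genes, 12 rose and 1 fell with SOX17, 13 were higher and 1 lower over the list alone, and 14 and 1 with the block (mean 1.54, camera adjusted p = 1.04e-14, and adjusted p = 0.121 with an estimated correlation). APOA2 rose by 3.74. AFP, a fetal plasma protein of yolk sac and liver, was the member that fell (−1.05, adjusted p = 0.0454), a call kept under 8 of 23 alternatives, and its change with SOX7 was −1.02 (adjusted p = 0.142, and 0.0486 with the clone as a block). All 21 basement membrane genes had positive changes with SOX17, and 10 rose, among them the laminin chains LAMB1 (2.45) and LAMA1 (2.11), the collagen COL4A1 (1.91) and the fibronectin FN1 (3.07). Over the list alone, and also with the block, 13 were higher (mean 1.09, camera adjusted p = 9.26e-14, and adjusted p = 0.157 with an estimated correlation). Several genes stand in more than 1 list, so that these tests overlap.

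**Figure D2:**
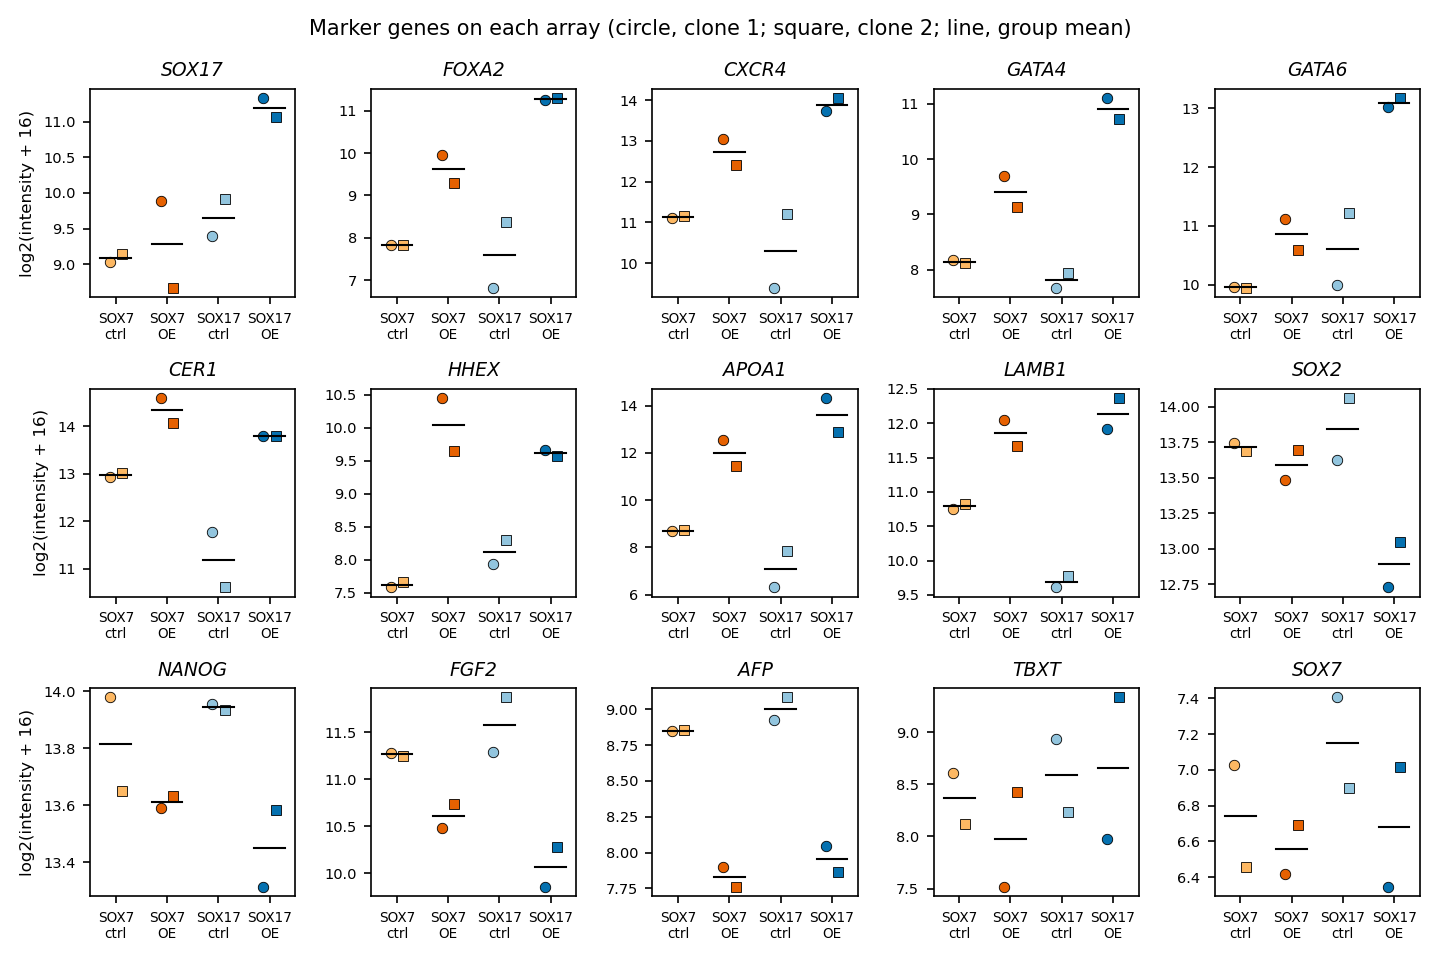
Log2(intensity + 16) of 15 marker genes on each of the 8 arrays, in panels with the 4 groups along the horizontal axis, circles for clone 1, squares for clone 2 and a line at each group's mean. FOXA2, CXCR4, GATA4 and APOA1 were highest in the SOX17 clones, and SOX2 and FGF2 were lowest there.

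Of 23 pluripotency genes measured, 6 fell with SOX17, none rose and 17 did not pass, 13 were lower and 1 higher over the list alone, and 14 were lower and 2 higher with the clone as a block (mean −0.55, camera adjusted p = 1.53e-06, and adjusted p = 0.11 with an estimated correlation; fry adjusted p = 0.00604). With SOX2 and FGF2, the Polycomb gene PHC1 (−1.33), USP44 (−1.22) and the telomere protein gene TERF1 (−1.15) were lower. NANOG had a log2 change of −0.50 (adjusted p = 0.179, and 0.0162 with the clone as a block), from 15758 ± 184 to 11215 ± 1471 (SD, n = 2).

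Adhesion and mesenchymal genes both included rises with SOX17. Of 15 epithelial adhesion genes, 4 rose, the keratins KRT8 (2.15), KRT19 (1.88) and KRT18 (1.36) and the desmosome gene DSP (1.26), 4 were higher over the list alone, and 6 were higher and 1 lower with the block (camera adjusted p = 0.00014, mean 0.59, and adjusted p = 0.157 with an estimated correlation). Of 13 mesenchymal transition genes, 5 rose, FN1, the integrin ITGA5 (2.19), the N-cadherin CDH2 (1.82), the gelatinase MMP2 (1.53) and the vimentin gene VIM (0.94, chosen after its value was seen), and 7 were higher over the list alone and with the block (camera adjusted p = 7.05e-07, mean 1.11, and adjusted p = 0.158 with an estimated correlation).

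Each of 3 signalling pathway lists had members that rose with SOX17. Of 17 Wnt genes 6 rose, with RSPO3, FRZB, SFRP1 (3.27) and FZD5 (1.56) as examples, 7 were higher over the list alone, and 7 were higher and 1 lower with the block (camera adjusted p = 3.08e-05, mean 1.12, and adjusted p = 0.157 with an estimated correlation). Of 15 BMP genes 4 rose, the ligand BMP2 (3.38), the BMP-responsive MSX2 (3.16) and MSX1 (1.80), and the pseudoreceptor BAMBI (1.46), and 7 were higher over the list alone and with the block (camera adjusted p = 6.32e-05, mean 1.06, and adjusted p = 0.157 with an estimated correlation). Of 17 Nodal and TGF-beta genes 4 rose, FST (2.46), CER1, BAMBI and the receptor ACVR1B (1.39), and the inhibin chain INHBE was lower (−1.66, chosen after its value was seen). There, 5 were higher and 1 lower over the list alone, and 5 and 2 with the block (camera adjusted p = 0.00255, mean 0.48, and adjusted p = 0.157 with an estimated correlation).

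All 20 cell cycle genes had negative changes with SOX17, with a mean of −0.32 (camera adjusted p = 0.000614, and adjusted p = 0.374 with an estimated correlation). None passed singly in limma, over all genes or over the list alone, and 6 were lower with the clone as a block. In 4 further lists that camera called, 1 gene rose in each: EOMES among 11 streak genes (adjusted p = 0.0326, and adjusted p = 0.312 with an estimated correlation), PAX6 (2.20) among 10 ectoderm genes (0.0486, and adjusted p = 0.389 with an estimated correlation), GATA3 (3.16) among 8 trophoblast genes (0.012, and adjusted p = 0.193 with an estimated correlation) and KIT among 9 germ cell genes (0.0274, and adjusted p = 0.188 with an estimated correlation). Adjusted over the list alone, 1 streak gene was higher, 3 ectoderm genes higher and 1 lower, 2 trophoblast genes higher and 4 germ cell genes higher. The block gave 1 streak gene higher and 1 lower over all genes, 4 ectoderm genes higher and 1 lower, 2 trophoblast genes higher and 4 germ cell genes higher. The streak gene TBXT had a log2 change of 0.06 (adjusted p = 0.965).

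The other 6 lists were not called with SOX17. KDR, a receptor for vascular endothelial growth factor, was lower (−1.31) in the mesoderm list (camera adjusted p = 0.818) and in the endothelium list (0.241). VIL1 was higher (3.07) and AFP lower in the liver and gut list (0.389). Among stress genes (0.421), HMOX1, the inducible heme oxygenase (2.59), and GADD45A (1.00) rose, and ASNS (−0.98) and CHAC1 (−1.72) fell. HPRT1 was lower (−0.86) in the housekeeping list (0.0832). Adjusted over the list alone, 3 stress genes were higher and 2 lower and 4 fibroblast genes higher and 1 lower, and the other 4 lists had the same counts as over all genes. Over all genes with the block, 3 stress genes were higher and 2 lower, 5 fibroblast genes higher and 3 lower, 1 mesoderm gene higher and 1 lower, and 2 housekeeping genes lower. In the fibroblast list (0.428), THY1 was lower (−0.93), and the list's mean was 9.22 and 9.87 (log2) on the SOX17 arrays and 9.17 and 9.40 on their controls, the higher values being those of clone 2.

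**Figure D3:**
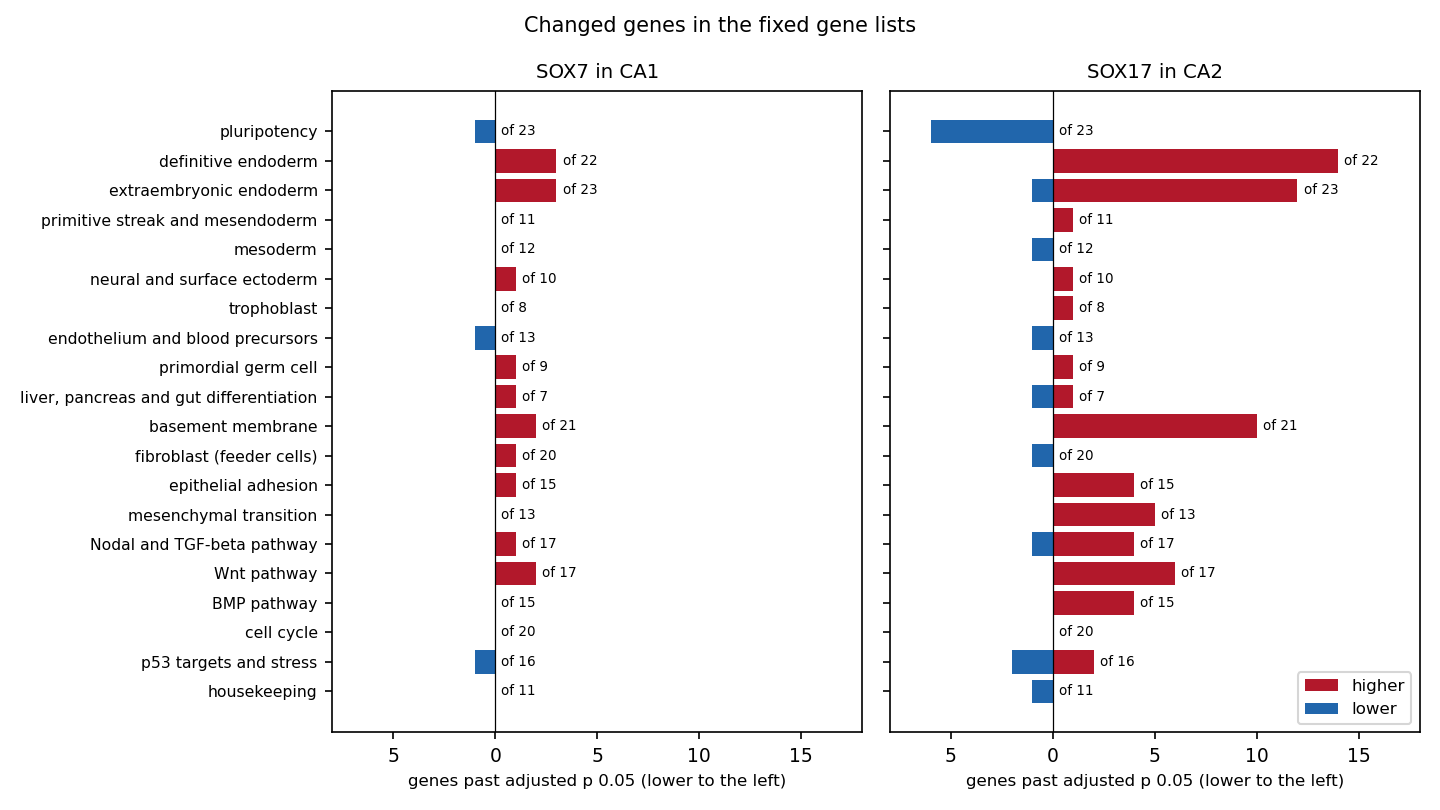
Number of called genes per fixed gene list, higher to the right and lower to the left, for the SOX7 and SOX17 responses, with 14 rises for definitive endoderm with SOX17 and 3 with SOX7. Bars start at 0 and lists overlap in their members.

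The third question was how far the responses share genes. Of the calls, 57 genes rose in both, where independent lists would share 2.93 (odds ratio 67.4, Fisher's exact test across genes p = 6.63e-64), 7 fell in both against 0.32 (odds ratio 30.5, p = 2.15e-08) and none moved in opposite directions. The genes higher in both include APOA1, APOA2, LINC00261, IGFBP5, HHEX, IHH, VIL1, ACSL1, LAMB1, DKK1 and KRT19. Those lower in both were NTS, ASNS, CAV1, TRIM22, DIAPH2, VSNL1 and the stress-induced DDIT4 (−1.06 with SOX7, −1.03 with SOX17). VSNL1 and DDIT4 were chosen after their values were seen. Of all SOX7 calls, 80 of the 83 rises and 22 of the 26 falls had the same sign with SOX17. The log2 changes correlated across the 14036 genes at r = 0.355 (Spearman's rho = 0.301). SOX7 clone 1 correlated with the SOX17 clones at 0.352 and 0.35, and SOX7 clone 2 at 0.162 and 0.125, beside 0.36 between the SOX7 clones and 0.518 between the SOX17 clones. Genes are not independent replicates. The contrasts share no array but share each gene's estimate of the spread, so that calls in the 2 responses are not independent. With only the arrays of each contrast 56 genes passed in both. Cre, and any change of drug with it, goes with over-expression in both lines by the titles. The shared changes therefore cannot be assigned to the transgenes alone. With the clone as a block 258 genes passed in both, and without the variance trend 2. The 64 genes called in both became 17 without SOX7 over-expressing 1, 15 without either SOX7 control, and 1 without the SOX7 clone 1 pair, an alternative chosen after seeing the data.

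The fourth question was which genes responded differently. CST1 had a log2 change of −0.59 with SOX7 and 5.13 with SOX17, a difference of 5.72 (SE 0.73, adjusted p = 0.0151). DNMT3L, a cofactor of DNA methylation, had −2.09 (adjusted p = 0.108, and 0.0412 with the clone as a block) and 3.27 (difference 5.36, SE 0.73, adjusted p = 0.0168). KCNJ16 (difference 5.23), NPPB, the natriuretic peptide of stretched heart muscle (5.10), CST4 (4.55), TMEM88 (4.48), CST2 (4.21) and TNNC1 (4.03) had higher changes with SOX17 too. The gap between the controls enters this difference. That gap, CA2 minus CA1, was called for CST1 (−3.05) and KCNJ16 (−2.93). NPPB, CST4, TMEM88, CST2 and TNNC1 also had lower mean intensities in the CA2 controls, while DNMT3L did not (131 in CA2, 115 in CA1). DNMT3L was at 14.5 on the SOX7 arrays and KCNJ16 at 17.6 in the SOX17 controls, so that their sizes depend on the constant added: with pseudocounts of 1 and 64 the differences were 6.39 and 4.02 for DNMT3L and 6.11 and 4.01 for KCNJ16. In the opposite direction were the proteoglycan gene SPOCK1 (−2.84, adjusted p = 0.0473), which rose by 2.50 with SOX7, DLK1 (−2.22) and PMEL (−2.22). Of 23 alternatives, the calls of SPOCK1 held in 6, of TMEM88 in 7, of PMEL in 10, of NPPB in 12, of CST2 and TNNC1 in 13 and of DLK1 in 14.

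In all, 30 genes differed, 27 with a higher and 3 with a lower signed change with SOX17. Of the 30, 5 had the larger response with SOX7. Over all 14036 genes, 1147 had an unadjusted p under 0.05 in limma, where chance gives 701.8. With the clone as a block 322 passed (233 higher, 89 lower), among them all 30. No gene passed in limma without the variance trend, where 1078 had an unadjusted p under 0.05, and quantile normalization left 14. Without the clone 1 SOX7 control 1 gene passed. Of the fixed lists, 11 differed with a preset correlation. The most distinct were extraembryonic endoderm (mean difference 0.77, camera adjusted p = 6.71e-09), BMP (1.34, 1.15e-08) and basement membrane (0.61, 1.75e-08), with adjusted p = 0.181, adjusted p = 0.181 and adjusted p = 0.216 with an estimated correlation. Definitive endoderm differed by a mean of 0.70 (6.83e-05, and adjusted p = 0.286 with an estimated correlation), and pluripotency by −0.33 (0.00298, and adjusted p = 0.181 with an estimated correlation). Adjusted over the list alone, 10 definitive endoderm genes had a higher and 2 a lower change with SOX17, 9 extraembryonic endoderm, 6 BMP and 5 basement membrane genes a higher one, and 1 pluripotency gene a higher and 3 a lower one. The ectoderm and cell cycle lists differed too when the clone was a block (camera adjusted p = 0.0426 and 0.0214, from 0.0711 and 0.0893), with adjusted p = 0.489 and adjusted p = 0.668 with an estimated correlation. BMP2 (difference 3.23), BAMBI (2.04) and HMOX1 (2.71) were the list members that passed singly, with the call of BMP2 kept under 8 of 23 alternatives.

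The last comparison was of the controls. Among the largest differences between the CA2 and CA1 control cultures were those of PEG3, MEG3 and CHCHD2. By their titles these are NoCre cultures of the SOX17 and SOX7 clones, so that line and clone origin go together. PEG3, a paternally expressed zinc finger gene, was at 4525 ± 907 in CA2 and 41.3 ± 20.8 in CA1 (SD, n = 2; log2 difference 6.34, adjusted p = 4.35e-07), and MEG3, a maternally expressed noncoding RNA, at 1762 ± 40.6 and 15.7 ± 12.9 (SD, n = 2; 5.87, adjusted p = 8.98e-05). CHCHD2, a mitochondrial and nuclear protein gene, was at 174.3 ± 105 in CA2 and 12933 ± 5298 in CA1 (SD, n = 2; −6.15, adjusted p = 6.98e-05). Also higher in CA2 were SNHG24 (6.55), NNAT (4.29), DPPA5 (3.96), SNORD114-3 (3.84), TSPYL5 (3.78) and QPCT (3.01). Lower there were ZNF257 (−4.11), CST1 (−3.05), KCNJ16 (−2.93), GASK1B (−2.67), ZNF354C (−2.56), SPRR3 (−2.47) and FOXQ1 (−2.16). CST1, KCNJ16, GASK1B and FOXQ1 were also named among the rises with SOX17, and both contrasts use the CA2 control arrays, so that a chance low value there adds to both.

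Between controls 24 genes were higher and 16 lower in CA2, 40 in all, and 1106 had an unadjusted p under 0.05. With the preparation batch as a block 399 genes passed (196 higher, 203 lower). In that fit the gap between the lines rests on their clone 1 arrays, over-expressing and control, and so on 1 clone per line. The clone 2 arrays enter only through the change with over-expression and through the spread. Without the variance trend 15 passed, and 78 did with only the 4 control arrays. Camera called 8 lists with the preset correlation: p53 targets and stress (adjusted p = 0.00276), extraembryonic endoderm (0.0102), basement membrane (0.0102), mesenchymal transition (0.0102), pluripotency (0.0129), ectoderm (0.0231), endothelium (0.0231) and primordial germ cells (0.0231). Each had an adjusted p = 0.556 with an estimated correlation. Of list members, DPPA2 (1.84) and DND1 (1.58) were higher in CA2, and CER1 (−1.78), FN1 (−1.68) and FST (−1.45) were lower.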

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

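The tests of the difference over all genes and over the fixed lists were planned, predictions for scaling and for mixed RNA were written before their results, and the other tests in this part, with the fits that leave out a clone pair, were chosen only after the results were seen.

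The responses to SOX17 in CA2 and to SOX7 in CA1 differed at 30 genes by the test of the difference itself. On the log2 scale, SOX17 minus SOX7, the differences were 5.72 for CST1, 5.36 for DNMT3L, 5.23 for KCNJ16, 5.10 for NPPB, 4.55 for CST4, 4.48 for TMEM88, 4.21 for CST2 and 4.03 for TNNC1. They were −2.84 for SPOCK1, −2.22 for DLK1 and −2.22 for PMEL. Members of fixed lists were BMP2 at 3.23, HMOX1 at 2.71 and BAMBI at 2.04. ANXA1 at 3.42, NTS at 2.53 and PHLDA1 at 2.14 are positive because these genes fell further with SOX7, and PHLDA1 was chosen after its values were seen. Of the fixed lists, 11 differed by camera with a preset correlation, with adjusted p-values from 0.181 to 0.286 with an estimated correlation.

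Of the 30 genes, 27 had the higher signed change with SOX17. Quantile normalization left the median size of the difference at 0.998 of its value (3.04 before, 3.03 after), with all 30 in the same direction. Their size and direction thus did not depend on this scaling. Another outcome was hardly possible, because the genes were chosen for large differences. Over all genes the median difference was −0.059 before and −0.03 after. The number of genes passing did depend on the scaling, with 14 of all those tested after it, so that scaling is not excluded for the count. A weak response of 1 SOX7 clone alone stays open: choosing the 27 genes by this test fixes low SOX7 values (medians 0.09 in clone 1 and −0.67 in clone 2 against 3.24 with SOX17, the stronger clone at 0.028 of the SOX17 value), and 0 genes passed in limma without the SOX7 clone 2 pair (480 at an unadjusted p under 0.05) but 35 without the clone 1 pair. Whether the transgene or the parent line sets the difference cannot be told apart, because 0 arrays carry SOX7 in CA2 or SOX17 in CA1. The biological difference between the factors therefore stays open beside that between the lines. For CST1 and KCNJ16, control values lower in CA2 than in CA1 (log2 difference −3.05 and −2.93, both called) enter the difference of the responses.

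Both SOX17 probe sets were higher than the control in SOX7 clone 1 and lower in SOX7 clone 2. RNA of the SOX17-expressing CA2 cells on the clone 1 array is argued against: 8 genes high in CA2 and low in CA1 gave a median share of 3.84% (from −9.18% to 7.45%), where the SOX17 probe set would need 23%. Over 21 definitive endoderm genes without SOX17, the response was larger in SOX7 clone 1 than in SOX7 clone 2 by a mean log2 value of 0.439 (1.43 against 0.99, larger for 16 of 21, permutation p = 0.04 across genes, which are not independent replicates), and also larger in SOX17 clone 1 than in SOX17 clone 2 (2.15 against 1.60). Since the clone 1 arrays of both lines share a preparation batch by the spike-ins, a stronger endoderm response of SOX7 clone 1 and an effect of that batch cannot be told apart. With 1 pair of arrays per clone, the difference between clones has no replicate.

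Neither SOX7 probe set was clearly higher on the arrays labelled SOX7 over-expressing, and both had low values. The one tested was at 69.4 against 114.2 on the control in clone 1 and at 87.6 against 71.8 in clone 2. The other, below the filter and not tested, had means of 41.3 against 35.7. A swap of the over-expressing and control arrays within a clone is argued against if both factors act in the same direction: of 184 genes that rose at least 4-fold with SOX17, 92.9% were higher on the array labelled over-expressing in SOX7 clone 1 and 74.5% in clone 2, against 50.5% and 55.9% of all genes. Probe sets outside the part of SOX7 in the transgene could give the low value, 78.5 on the over-expressing arrays, and so could a transgene with little transcript. No probe set known to lie inside the transgene was used here to decide between these.

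Among the control probe sets, which were left out of all tests of genes and from which the preparation batches were read, the poly-A spike-in dap was 42.1-fold higher on the SOX7 clone 2 arrays than on the SOX17 clone 2 arrays.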

How the results depend on the processing

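Leaving out clone pairs and the batch block for the controls were chosen after seeing the data, and the cause of a shift was not tested unless stated. Of 195 calls of named genes, 45 held under every alternative run for them, but of the SOX7 calls only those of NTS, ACSL1 and DLK1 did. Of the 21 lists called with SOX7 or SOX17, at least 17 held under each alternative, all of which kept the preset correlation. With an estimated correlation camera called none of the 21, the lowest adjusted p-values being 0.28 with SOX7 and 0.11 with SOX17. The correlation alone does not account for this loss. Pluripotency with SOX17 had an estimated correlation of 0.003, below the preset 0.01, and its camera p still went from 3.82e-07 to 0.00552. The calls of LGI2, FST, TEK, DDIT4, LIFR, SERPINE2 and PHLDA1 with SOX7 and of AFP, VIM, HLA-DRA, INHBE, MSX1, PSAT1, SLC7A5, PSME1 and SP110 with SOX17, of SPOCK1, PHLDA1, TMEM88, BMP2, PMEL and ANXA1 in the difference and of SPRR3, KCNJ16, FN1, GASK1B, DPPA2 and MEST between controls failed in more alternatives than they held in. No named gene that was called changed direction. The median of all genes stayed within 0.1 (log2) of 0 under each scaling. Low intensities near background limit genes such as SOX7.

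Quantile normalization left 14 genes whose responses differ, and testing every probe set left 12. Without the variance trend, 8 genes passed with SOX7, 192 with SOX17, 2 in both, 15 between controls and 0 in the limma test of the difference, where 1078 had an unadjusted p under 0.05. With only the control arrays, 78 passed between controls. At an adjusted p under 0.1, counts were 182 (SOX7), 1032 (SOX17), 54 (difference), 64 (controls) and 108 (both).

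With the clone as a block, 441 genes passed with SOX7, 1971 with SOX17, 322 for the difference and 258 in both. The batch block, in which the gap between the lines rests on the clone 1 arrays, gave 399 between controls. Pairing removes the spread between clones, and all calls of the fit without it held for the responses and their difference. Of the lists with SOX7 and SOX17, the block ended only the call of BMP with SOX7, and it added that of cell cycle with SOX7.

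Leaving out 1 array leaves a lone sample in its group, which is assumed to vary like the other groups. SOX7 calls ranged from 19 to 140, and were 33 without SOX7 over-expressing clone 1, 22 without its control and 19 without control 2. SOX17 calls ranged from 360 to 790, and were 360 without SOX17 control 1 and 426 without over-expressing 2. Genes that differ ranged from 1 to 111, with 111 and 13 without SOX7 over-expressing 1 and 2, 1 and 6 without SOX7 controls 1 and 2, 3 without SOX17 control 1 and 7 without SOX17 over-expressing 2. Control differences ranged from 8 to 59, with 14 and 12 without SOX7 controls 1 and 2 and 8 and 26 without SOX17 controls 1 and 2. The overlap ranged from 15 to 81, with 17 without SOX7 over-expressing 1 and 15 without either SOX7 control. Lists called ranged from 5 to 8 with SOX7 and from 10 to 15 with SOX17.

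Without the SOX7 clone 1 pair, 4 genes and 4 lists passed with SOX7, 22 genes between controls and 1 in both. Without the SOX7 clone 2 pair, 20 passed with SOX7, 17 between controls, 15 in both and 0 in the limma test of the difference (480 at an unadjusted p under 0.05). Without the SOX17 clone 1 pair, 220 passed with SOX17, 2 for the difference and 8 between controls. Without the SOX17 clone 2 pair, these were 276, 8 and 21. Fewer arrays remain in each of these fits.

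Signs reversed only for log2 changes that were not called. TBXT with SOX17 was −0.024 after quantile normalization and −0.967 without the SOX17 clone 2 pair, and ranged from −0.617 (without SOX17 over-expressing 2) to 0.744 over single arrays left out, with −0.287 without SOX17 control 2. With SOX7, leaving out single arrays gave SOX17 from −0.421 to 0.792, TBXT from −0.846 to 0.063, SOX7 from −0.47 to 0.10 and CST1 from −1.261 to 0.082. The first 2 reversed without over-expressing 1, SOX7 without control 1 and CST1 without over-expressing 2. Without the clone 1 pair SOX17 was −0.477, TBXT 0.31, SOX7 0.239 and SOX2 0.012, and without the clone 2 pair CST1 was 0.091. SOX7 in the SOX17 contrast was 0.122 without the SOX17 clone 1 pair.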

Other observations

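The tests of hypotheses in this part, and the genes named in it for the first time, were chosen only after the results were seen. Of further genes that rose in both responses, haptoglobin HP rose by a log2 value of 1.93 with SOX7 and 3.69 with SOX17 (limma adjusted p = 0.024 and 0.000104), complement C5 by 2.17 and 2.33, and the trefoil peptide TFF1 by 2.70 and 2.83. PDZK1, a scaffold of epithelial transporters, rose by 2.47 and 4.05, the Wnt-responsive receptor LGR5 by 2.03 and 3.33, and the leukemia inhibitory factor receptor LIFR by 1.38 and 2.93. The laminin chain LAMA4 (2.44 and 2.19), NPNT (2.37 and 2.40) and the protease inhibitor SERPINE2 (1.07 and 1.81) rose too. Of kept probe sets without a single gene symbol, 5694 in all, 16 rose and 3 fell with SOX7 and 96 rose and 24 fell with SOX17 when every probe set was tested.

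Besides MYL7 and TNNC1, the myosin light chains MYL4 (log2 change 3.15) and MYL3 (3.10), the natriuretic peptide NPPB (3.52) and the giant sarcomere protein TTN (2.01) rose with SOX17, which makes 6 of 15 genes of a cardiac muscle list written after these rises were seen. The mean change of the list was 1.37 (camera p = 3.4e-05, and p = 0.0802 with an estimated correlation), and with SOX7 it was 0.08 (camera p = 0.99, and p = 0.995 with an estimated correlation). Between the controls the same list had a mean difference of −0.53, CA2 minus CA1 (camera p = 0.00308, and p = 0.171 with an estimated correlation), with MYL7 at 389.1 against 1530.5 and NPPB at 858.9 against 2467.6, and the change with SOX17 is measured from those CA2 control arrays. A cardiac muscle programme as a whole is one hypothesis. It predicts rises of the members that were not called, and these had a mean change of −0.03 (camera across genes p = 0.878, and p = 0.907 with an estimated correlation). The bound first written against it was such a mean. It was replaced after the result was seen by one on the whole list, since a list that leaves out the called genes excludes nothing, and the hypothesis stays open with no evidence from the rest of the list. The same replacement was made for the lists of ATF4 targets and of interferon genes.

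Of 36 targets of ATF4, a factor that induces genes of amino acid synthesis and stress, 3 fell with SOX7, and 8 fell and 1 rose with SOX17. ASNS and DDIT4 fell in both, SLC7A11 with SOX7 (−1.23), and PHGDH (−1.26), PSAT1 (−0.81), AARS1 (−0.87), PCK2 (−0.99), CHAC1 and INHBE with SOX17, while the amino acid transporter SLC7A5 rose (0.89). Lower activity of ATF4 is a hypothesis consistent with the list's mean. Of the 36, 35 had negative changes with SOX7 (mean −0.57, camera p = 2.43e-19, and p = 0.0166 with an estimated correlation) and 30 with SOX17 (mean −0.42, camera p = 1e-06, and p = 0.0973 with an estimated correlation). Members that were not called had means of −0.52 with SOX7 and −0.25 with SOX17, with a larger camera p of 0.00264 (SOX17), and p = 0.209 there with an estimated correlation. The SOX17 change is again measured from CA2 controls, where the list lay above the CA1 controls by a mean of 0.12 (camera p = 0.0278, and p = 0.387 with an estimated correlation). The state of the culture medium at harvest, or Cre, which marks the over-expressing arrays of both lines, could act in the same way. Neither was tested.

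Of 22 imprinted genes measured, 6 were called between the controls, all higher in CA2, where 0.063 are expected: PEG3, MEG3, SNHG24, SNORD114-3, NNAT and MEST (log2 difference 1.04, adjusted p = 0.0384, a call kept under 10 of 22 alternatives). SNHG24, SNORD114-3 and MEG3 share a locus, and 5 of the 6 had been seen before the list was written. Without these 5, Fisher's exact test across genes gave p = 0.0416, which rests on MEST alone. The 16 members that were not called had a mean of 0.21 (camera across genes p = 0.625, and p = 0.627 with an estimated correlation), with PLAGL1 (−1.56), BLCAP (−0.75) and GRB10 (−0.66) in the other direction. The lines, or the clones taken from them, may differ in imprinting status, a hypothesis that methylation values, not analysed here, would test. PEG3 had log2 changes of 0.30 with SOX7 and −0.51 with SOX17, neither of them called.

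One hypothesis, that of 1 shared programme at a lower amplitude with SOX7, predicts no gene with a larger response with SOX7, and 5 had one past the test of the difference, ANXA1, DLK1, NTS, PHLDA1 and SPOCK1. Their calls held in 11, 14, 19, 6 and 6 of 23 alternatives, no gene passed the limma test of the difference without the variance trend (1078 at an unadjusted p under 0.05) and 1 passed without SOX7 control 1, so that the hypothesis stays open. Of these 5, NTS alone was called in both. Among all genes called in both, the change was larger in size with SOX7 for each of the 7 falls and for 17 of the 57 rises, and only that of NTS passed the test of the difference.

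Interferon and antigen presentation genes were among the falls with SOX17. Of 24 listed, 6 fell, HLA-DRA, IDO1, TRIM22, UBE2L6 (−1.35), SP110 (−1.21) and PSME1 (−0.86), and ISG15 rose (1.63). The mean was −0.60 (camera p = 0.00172, and p = 0.0469 with an estimated correlation). With SOX7, TRIM22 fell, HLA-B rose (1.27, limma adjusted p = 0.0266) and the mean was 0.03 (15 of 24 positive, camera p = 0.324, and p = 0.422 with an estimated correlation). Between the controls, CA2 minus CA1, it was 0.24 (18 of 24 positive, camera p = 0.0104, and p = 0.0811 with an estimated correlation), and the fall with SOX17 is measured from those CA2 control arrays. A lower level of the whole group is a hypothesis. The members that were not called leave it open, with a mean of −0.38 (camera across genes p = 0.198, and p = 0.381 with an estimated correlation).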
